A study of Mycolicibacterium smegmatis with 6 samples.

How the data were processed

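RNA was measured in 6 libraries, 3 of wild-type Mycolicibacterium smegmatis MC2 155 (WT) and 3 of its msoA mutant (KOmsoA), all from logarithmic phase. Groups and replicate numbers were taken from the genotype and title labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA, fragmented, made into strand-specific libraries with random primers and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, CASAVA 1.8 was used; the aligner, the counting program, its handling of strand and of reads with several matches, and the annotation are not given in the sources used here. Random priming and PCR enrichment without molecular identifiers mean that counts are not independent molecules, so counting intervals cover counting error only.

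The authors deposited a table of 6536 genes with raw read counts and with FPKM per library, as the file headers name them. The counts are whole numbers with totals of 4030254 to 7099167 per library, and they carry the analysis; 3 counts, the limit that a count of 0 allows, correspond to 0.423 to 0.744 CPM. The authors' deposited FPKM values follow from the counts, the gene span and the library total except for 562 of 39216 values (relative tolerance 0.0001), and were not used for tests. No column lacked a sample. Gene coordinates are those of the deposited table, which uses the chromosome sequence of assembly ASM1500v1. A reference gene table of that assembly matched 6480 of the 6536 genes, 5788 with the same coordinates, and gave a symbol for 1001. It holds no product names and no strand here, and neither source names msoA or its locus, so the planned comparison of msoA in every sample could not be made and no locus was assigned to msoA from the counts.

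Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had no covariate, since the labels name no batch. Abundances are TMM-normalized CPM given as mean ± SD, and the SE of a log2 fold change is its size divided by the square root of the F statistic. All log2 fold changes are KOmsoA over WT. The biological coefficient of variation was 0.075. Of 173 genes whose protein is identical to another gene's, 12 passed the filter and none was called (edgeR, with 2 at an unadjusted p under 0.05; none by DESeq2 or limma-voom), so no called gene has an identical protein copy. Copies of RNA genes were not compared, and overlapping genes can share reads.

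The locus tags and product words of the gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives unless stated otherwise. Of 34 lists, 20 were given as locus tags, some with words to be found in product names, and the others by product words alone. Because no product names were held, gene symbols or biotypes stood in for product words; these symbol patterns, and the removal of MSMEG_3926 from the hydrogenases because its symbol names another function, were set after the results of a first edgeR test of these counts had been seen, so these members were not chosen blind to the data. They fill 7 lists completely (ribosomal proteins, aminoacyl-tRNA synthetases, sigma factors, peptidoglycan and cell division, osmoprotection and trehalose, sulfur assimilation, stable RNAs). They also add members to 9 others, including 5 of the 22 cycle genes. Some symbol matches name another function: cysT and glnT among the synthetases, cysS under sulfur assimilation, MSMEG_4921 under Mce, and ftsH and ftsY under cell division. The lists were tested again without these members, a choice made after the data were seen. The DosR, cytochrome bd, mycolic acid and cholesterol lists rest on locus tags alone. The 7 lists with no symbol equivalent (universal stress proteins, TetR and MarR regulators, ABC transporters, cytochromes P450, monooxygenases, PE and PPE proteins) were not analysed here. The 27 lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and each list's calls were also counted after adjustment over the list alone.

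Genes named in the text follow a rule that gave 83 genes. It takes the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 CPM and fully separated groups. It adds the 2 called members of each list with the largest rise and the 2 with the largest fall, or the member with the smallest p. It adds the first, last and most changed gene of the 3 longest runs in each direction, and the most abundant gene or any over 5% of a library. Other genes, such as the neighbours of MSMEG_6731 and further members of lists and runs, were chosen after their values were seen. Of the 75 named genes that were called, 43 kept the call in each of the 6 leave-one-out fits and 32 lost it in at least 1.

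Runs of neighbouring genes were counted in locus order without strand, against 10000 permutations of the calls. Library totals and stable RNA shares were compared with an exact permutation test. The share of MSMEG_6731 was given an exact (Clopper-Pearson) interval at a confidence level of 95%. Alternatives were RLE and upper-quartile factors, no low-count filter, a mean of at least 10 CPM, a replicate term, stable RNA genes left out, DESeq2 1.42.0, limma-voom, edgeR's glmTreat against a log2 fold change of 1, an adjusted p under 0.01, each library left out in turn, an estimated correlation and fry for the lists, and runs of at least 4 genes. A correction for gene span, and the runs under alternatives other than the replicate term, single libraries left out and 4 genes, were added after the data were seen.

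The procedures were tested on simulated counts for the KOmsoA and WT comparison. Over 5824 genes edgeR recovered 65% of genes changed by 0.5 on the log2 scale and 94.9% of those changed by 1, with 8 false calls among 181. A shifted list was found and none of 20 unshifted lists was called, and a planted run of 6 genes was found. Simulated genes varied independently of each other, so this cannot show how the list test behaves where members vary together. Other tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.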

Results

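The data set compared the transcriptome of wild-type Mycolicibacterium smegmatis MC2 155, a fast-growing mycobacterium used as a laboratory model, with that of a mutant of the gene msoA, labelled KOmsoA. Both strains were harvested in logarithmic phase in 7H9 broth. Strand-specific libraries were made from total RNA after ribosomal RNA removal, 3 for each strain. The WT libraries held 5003840, 7099167 and 4030254 gene counts and the KOmsoA libraries 4969092, 6900453 and 5138809. The totals did not differ detectably between the strains (exact permutation test, two-sided, p = 0.9), where 0.1 is the smallest p that 3 against 3 samples allow. Stable RNA genes took 3.59% ± 0.0526 (SD, n = 3) of the KOmsoA counts and 3.48% ± 0.194 (SD, n = 3) of the WT counts (exact permutation test, p = 0.5). Most of this was the transfer-messenger RNA ssrA, at a mean of 2.69% of KOmsoA and 2.55% of WT counts. Ribosomal RNA genes took 0.0252% of KOmsoA and 0.0260% of WT counts. The most abundant gene was dnaK (MSMEG_0709), the Hsp70 chaperone gene, with between 2.91 and 3.52% of each library. Its log2 fold change of -0.12 (SE 0.06) did not pass (edgeR adjusted p = 0.25), and was -0.01 without WT replicate 3 (adjusted p = 0.907).

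Libraries of one strain correlated across genes with r of 0.990 to 0.995 on the log2 scale, and libraries of different strains with r of at most 0.991. WT replicate 3 stood apart from the other WT libraries. Its counts differed from theirs by a chi-square of 9.55 and 9.86 per degree of freedom, against 2.66 between WT replicates 1 and 2 and 2.61 to 3.59 among the KOmsoA libraries. The labels describe harvested cells being divided into tubes of equal biomass and do not say that the replicates were separate cultures. Every edgeR p-value below therefore measures only the spread between these samples, which may be technical. The p-values for lists and runs start from the same samples. They compare list members with other genes, or the placing of calls along the chromosome with permuted calls.

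The comparison of the strains asked which transcripts differed in the msoA mutant during logarithmic growth. A pair of neighbouring genes, MSMEG_6731 and MSMEG_6732, changed by far more than any other called gene. Transcripts of MSMEG_6731 were almost absent from KOmsoA, and those of MSMEG_6732 rose from 34.6 to 3500 CPM, the count scaled to library size. Beyond this locus most changes were small. Of 5836 genes tested with edgeR's quasi-likelihood test, 663 (11.4%) passed an adjusted p of 0.05, 341 higher and 322 lower in KOmsoA. Their median absolute log2 fold change was 0.39, with an interquartile range of 0.29 to 0.55. Of these genes 35 changed by at least 1 on the log2 scale, 22 upward and 13 downward. In 662 of the 663 genes every KOmsoA library lay on the same side of every WT library. Of all tested genes 30.6% did so, where chance gives 10%. The number of calls was 407 without WT replicate 2, 327 without KOmsoA replicate 2 and 339 without KOmsoA replicate 3. It was highest, at 797, without WT replicate 3. Tested with edgeR's glmTreat against a log2 fold change of 1, only MSMEG_6731 and MSMEG_6732 passed.

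**Figure D1:**
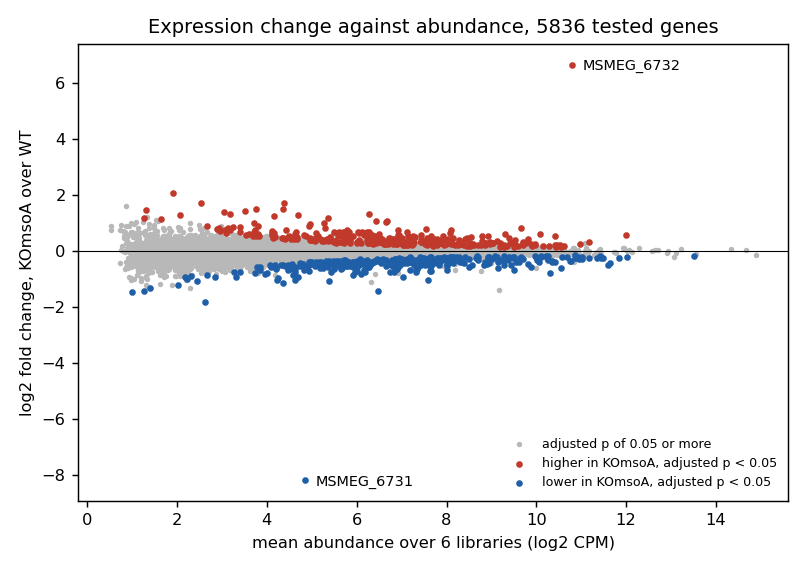
Each point is one of 5836 tested genes, with mean abundance over the 6 libraries (log2 CPM) on the x axis and the log2 fold change of KOmsoA over WT on the y axis, and red and blue points passed an edgeR adjusted p of 0.05. MSMEG_6732 at 6.67 and MSMEG_6731 at -8.17, a fitted value that depends on the prior count because KOmsoA held only 3 counts, lie apart from the other called genes.

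MSMEG_6731 lies at 6777839 to 6778417 on the ASM1500v1 chromosome and MSMEG_6732 at 6778536 to 6779126, with 118 bp between them. Both are annotated as protein-coding. The WT libraries held 227, 419 and 262 counts of MSMEG_6731, and the KOmsoA libraries 0, 2 and 1. Relative to library size KOmsoA held 0.310% of the WT level of MSMEG_6731 (95% exact interval 0.0639 to 0.910%). This is a 322-fold lower level, with an interval of 110-fold to 1565-fold that covers counting error only (edgeR adjusted p = 1.55e-08). MSMEG_6732 rose from 34.6 ± 2.96 CPM (SD, n = 3) in WT to 3500 ± 82.8 CPM (SD, n = 3) in KOmsoA, a log2 fold change of 6.67 (SE 0.07, edgeR adjusted p = 4.09e-16). On the other side of MSMEG_6731, MSMEG_6729 rose by a log2 fold change of 1.33 (SE 0.09, edgeR adjusted p = 3.19e-06). MSMEG_6730, which overlaps MSMEG_6729, rose by 0.38 (SE 0.07, edgeR adjusted p = 0.00386). The gene directly after MSMEG_6732, MSMEG_6733, had a log2 fold change of 0.00 (SE 0.09, edgeR adjusted p = 0.989), while MSMEG_6735 fell by 0.81 (SE 0.10, edgeR adjusted p = 0.000235). The sources used here do not name the locus of msoA, so its own expression is not given.

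**Figure D2:**
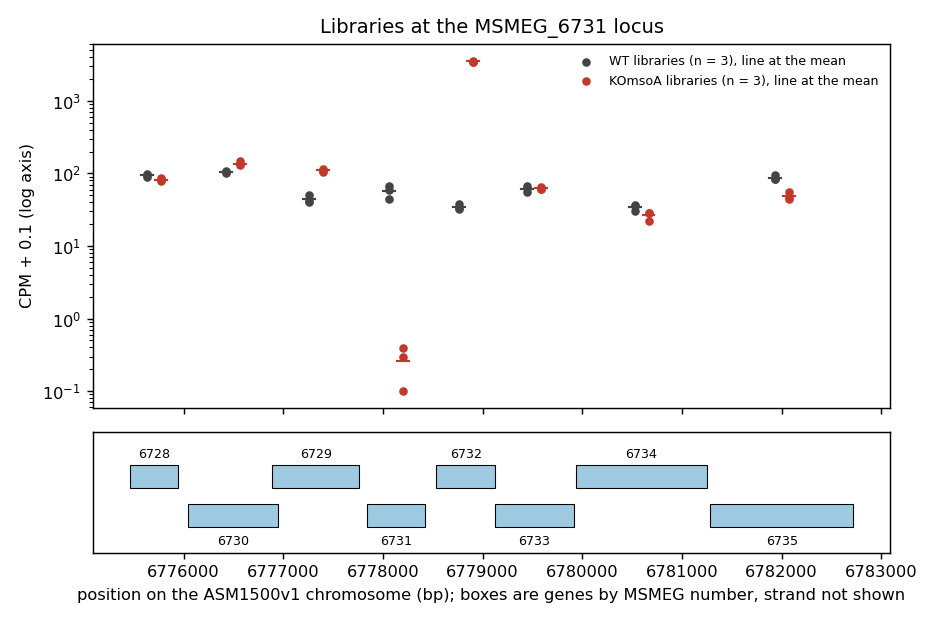
The upper panel gives the abundance (CPM plus 0.1, log axis) of 8 neighbouring genes in each WT (grey) and KOmsoA (red) library, with a line at the mean of 3 libraries, and the lower panel maps the genes to scale on the ASM1500v1 chromosome, without strand. The KOmsoA libraries lie near the floor at MSMEG_6731 and at a mean of 3500 CPM at MSMEG_6732, against 34.6 CPM in WT.

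Among genes of at least 10 CPM with fully separated groups, the largest rise after MSMEG_6732 was in MSMEG_2278, from 9.52 ± 2.44 to 32.3 ± 6.09 CPM (SD, n = 3; log2 fold change 1.73, SE 0.19, edgeR adjusted p = 0.000104). MSMEG_5151 rose 2.83-fold (SE 0.25 on the log2 scale), to 19.7 ± 6.23 CPM (SD, n = 3) in KOmsoA. MSMEG_6792 also rose 2.83-fold (SE 0.20), from 11.1 ± 4.14 CPM (SD, n = 3) in WT. MSMEG_3708 rose by a log2 fold change of 1.44 (SE 0.25). Several rises lay in close neighbours. MSMEG_6791 (1.27, SE 0.15) lies beside MSMEG_6792, and MSMEG_5153 (1.19, SE 0.14) close to MSMEG_5151. The adjacent genes MSMEG_0147 and MSMEG_0148 both had a log2 fold change of 1.10 (SE 0.08), from 54.6 ± 3.85 to 118 ± 2.83 CPM and from 65.1 ± 4.75 to 140 ± 5.76 CPM (SD, n = 3). MSMEG_0293 (1.29, SE 0.15) and MSMEG_6453 (1.04, SE 0.09) rose as well. The edgeR adjusted p of the genes in this paragraph lay between 3.19e-06 and 0.00234, apart from that of MSMEG_6732, and each call held with any 1 library left out.

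The largest fall after MSMEG_6731 under the same criteria was in MSMEG_2570, from 128 ± 7.90 CPM in WT to 48.2 ± 5.24 CPM in KOmsoA (SD, n = 3; log2 fold change -1.41, SE 0.09, edgeR adjusted p = 1.95e-06). Its neighbour MSMEG_2569 also fell (-1.01, SE 0.14). The adjacent genes urtA (MSMEG_2982) and urtB (MSMEG_2981), whose symbols belong to a urea ABC transporter, fell by log2 fold changes of -1.01 (SE 0.08, edgeR adjusted p = 1.48e-05) and -0.84 (SE 0.15, edgeR adjusted p = 0.0026). Further falls were in MSMEG_5385 (-1.15), MSMEG_0226 (-1.05), MSMEG_0572 (-1.03), MSMEG_1711 (-0.96), MSMEG_5557 (-0.93), MSMEG_4450 (-0.90) and MSMEG_2526 (-0.83). WT replicate 3 held 253 CPM of MSMEG_4450, against 126 and 132 CPM in the other WT libraries, and its log2 fold change was -0.52 without that library. The call of MSMEG_4450 was lost without KOmsoA replicate 2 or KOmsoA replicate 3 (edgeR adjusted p up to 0.0761), and DESeq2 did not call it.

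Genes of the DosR regulon, the mycobacterial response to hypoxia and dormancy, were lower as a group in KOmsoA. Of the 12 listed members 9 fell over all genes tested, and 10 when adjusted over the list alone. All 12 had a negative log2 fold change, with a median of -0.26 (camera adjusted p = 4.06e-05; adjusted p = 0.427 with an estimated correlation). MSMEG_3940 (-0.38, SE 0.09), MSMEG_3941 (-0.35, SE 0.08), MSMEG_3945 (-0.34, SE 0.06) and MSMEG_3950 (-0.30, SE 0.04) were among those that fell. The regulator gene dosR (MSMEG_5244) had a log2 fold change of -0.12 (SE 0.05) that did not pass (edgeR adjusted p = 0.154). Listed genes on both sides of dosR were called lower. They were MSMEG_5241 (-0.24), MSMEG_5242 (-0.28), MSMEG_5243 (-0.29), MSMEG_5245 (-0.23) and MSMEG_5246 (-0.24), with SE of 0.04 to 0.07. All listed members lay between MSMEG_3932 and MSMEG_3950 or between MSMEG_5241 and MSMEG_5246, not spread over the chromosome. The number of called members was 4 without WT replicate 2, 5 without KOmsoA replicate 2 and 10 without WT replicate 3. MSMEG_3940 and MSMEG_3941 both lost their call without WT replicate 2 or KOmsoA replicate 2. MSMEG_3940 lost it also without KOmsoA replicate 1 (edgeR adjusted p up to 0.111) and MSMEG_3941 also without KOmsoA replicate 3 (up to 0.0815).

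The genes of cytochrome bd oxidase, a high-affinity terminal oxidase, were also lower. MSMEG_3233, the cydA gene, fell from 1593 ± 431 to 942 ± 32.5 CPM (SD, n = 3; log2 fold change -0.76, SE 0.13, edgeR adjusted p = 0.00232). Its neighbour cydB (MSMEG_3232) fell from 694 ± 33.3 to 557 ± 30.8 CPM (SD, n = 3; -0.32, SE 0.06, edgeR adjusted p = 0.00317). The remaining member, cydD (MSMEG_3231), had a log2 fold change of -0.10 (SE 0.07) and did not pass. Thus 2 of 3 members fell, over all genes and adjusted over the list alone (median -0.32; camera adjusted p = 0.0276; adjusted p = 0.427 with an estimated correlation). WT replicate 3 held 2089 CPM of MSMEG_3233, against 1372 and 1317 CPM in the other WT libraries, and the log2 fold change without it was -0.51. The camera call was lost without KOmsoA replicate 1 (adjusted p = 0.0541) and with genes under 10 CPM left out (adjusted p = 0.051).

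Mycolic acid synthesis genes, which build the long-chain lipids of the mycobacterial outer membrane, were lower as a group. Of 18 members 7 fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone (median -0.16; camera adjusted p = 0.0115; adjusted p = 0.438 with an estimated correlation). Of the 7 falls 5 were in the adjacent genes MSMEG_4325 (-0.33, SE 0.10), acpM (-0.42, SE 0.06), kasA (-0.36, SE 0.05), kasB (-0.39, SE 0.05) and MSMEG_4329 (-0.45, SE 0.05). The others were MSMEG_4757 (-0.31, SE 0.05) and fadD32 (-0.22, SE 0.05), and 10 members were not called. The called falls thus lay mostly in 1 stretch of the chromosome. The symbols acpM, kasA and kasB belong to fatty acid synthase II. The member that rose, MSMEG_3580, listed as an antigen 85 mycolyltransferase gene, went from 203 ± 12.6 to 348 ± 24.4 CPM (SD, n = 3; log2 fold change 0.78, SE 0.07, edgeR adjusted p = 2.18e-05). The enoyl reductase gene inhA (MSMEG_3151) had a log2 fold change of 0.02 (SE 0.06, edgeR adjusted p = 0.832). MSMEG_4325 lost its call without WT replicate 1, WT replicate 2, KOmsoA replicate 1 or KOmsoA replicate 2 (adjusted p up to 0.166), and its log2 fold change was -0.22 without KOmsoA replicate 2.

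Genes for cholesterol ring degradation were lower as a group as well. Of 8 members 3 fell, and 6 when adjusted over the list alone (median -0.27; camera adjusted p = 0.0115; adjusted p = 0.427 with an estimated correlation). Among them were the regulator gene kstR (MSMEG_6042, -0.39, SE 0.06, edgeR adjusted p = 0.00157) and the monooxygenase gene hsaA (MSMEG_6038, -0.36, SE 0.08, edgeR adjusted p = 0.0087). In direction 7 members were lower and 1, hsaB, higher. Neither hsaB (0.11, SE 0.11) nor hsaC (-0.08, SE 0.08) passed (edgeR adjusted p = 0.572 and 0.591). The number of called members was 5 without WT replicate 3. It was 1 without KOmsoA replicate 2 or KOmsoA replicate 3, and hsaA lost its call there (adjusted p up to 0.0596).

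Genes listed under the tricarboxylic acid and glyoxylate cycles were lower too. The list also holds prpD (-0.17, SE 0.18) and prpB (-0.70, SE 0.29), whose symbols belong to the methylcitrate cycle. Neither was called, and the list was not tested without them. Of 22 members 5 fell and 0 rose by edgeR, and 8 fell when adjusted over the list alone (median -0.16; camera adjusted p = 0.0115; adjusted p = 0.601 with an estimated correlation). In all, 11 members had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 6. The largest falls among called members were in MSMEG_4646 (-0.38, SE 0.05, edgeR adjusted p = 0.000326) and MSMEG_4645 (-0.36, SE 0.06, edgeR adjusted p = 0.00107), listed as subunits of a ketoglutarate ferredoxin oxidoreductase. The number of called members was 3 without WT replicate 2, KOmsoA replicate 2 or KOmsoA replicate 3, and 6 without WT replicate 1.

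**Figure D3:**
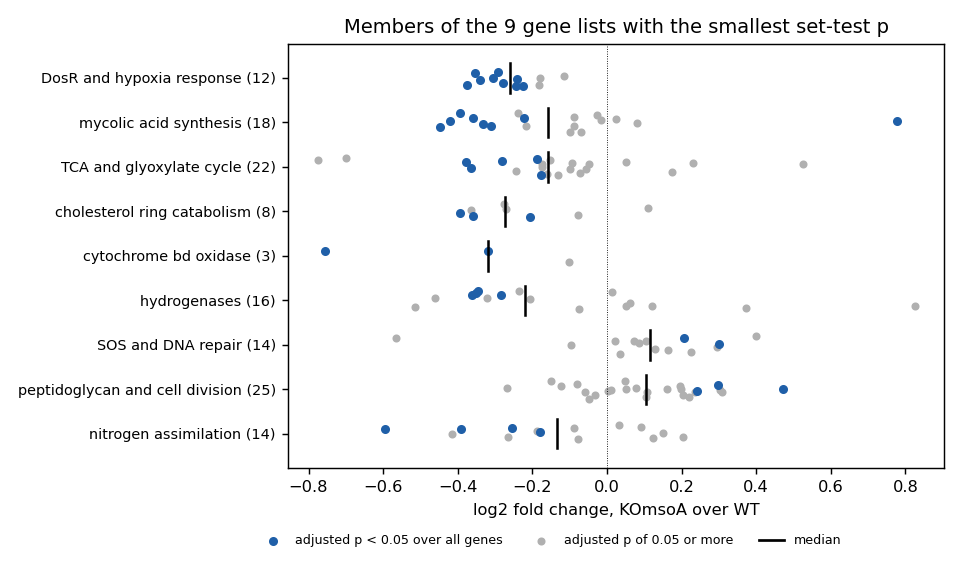
Points are the log2 fold changes (KOmsoA over WT) of the tested members of the 9 gene lists with the smallest camera p, with the number of tested members in brackets, coloured points passed an edgeR adjusted p of 0.05 over all genes, and the line is the list median. All 12 members of the DosR list and all 3 of the cytochrome bd list lie below 0, while MSMEG_3580 lies at 0.78 among mycolic acid genes with a median of -0.16.

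The other 22 lists did not pass the camera test. In energy metabolism, 0 of the 8 F1Fo ATP synthase genes (median -0.02, adjusted p = 0.757), the 10 nuo genes of NADH dehydrogenase type I (0.23, 0.426) and the 6 genes of the cytochrome bcc-aa3 branch (-0.08, 0.482) were called by edgeR, DESeq2 or limma-voom, or adjusted over the list alone. At an unadjusted p under 0.05 they held 0, 0 and 1 genes. Their members with the smallest p were MSMEG_4939 (-0.10, SE 0.05), MSMEG_2057 (0.53, SE 0.25) and qcrA (-0.10, SE 0.04). The nuo genes were scarce, with KOmsoA means from 1.79 CPM (nuoI) to 8.11 CPM (MSMEG_2051), and 10 of 14 listed were tested. Of these 8 were higher and 2 lower in KOmsoA, so a shift of this list could have been missed. Of 16 hydrogenase genes 4 fell, and 5 adjusted over the list alone (median -0.22, camera adjusted p = 0.136). They included the maturation gene hypB (-0.36, SE 0.08) and MSMEG_2720 (-0.35, SE 0.07). hypB lost its call without KOmsoA replicate 3 (edgeR adjusted p = 0.0635).

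In translation, 7 of 53 ribosomal protein genes rose and 2 fell, and 9 rose and 2 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.482). rplL (0.50, SE 0.11) and rplP (0.34, SE 0.07) were higher, rpsF (-0.29, SE 0.08) and rpsP (-0.28, SE 0.08) lower. Of 16 genes listed by symbol as aminoacyl-tRNA synthetases argS (-0.41, SE 0.09) and aspS (-0.20, SE 0.05) fell, as they did adjusted over the list alone (median -0.08, camera adjusted p = 0.423). This list holds cysT, a sulfate transport gene, and glnT, whose symbol is of the glutamine synthetase type. With these left out, 2 of 14 members fell, and 3 adjusted over the list alone (median -0.08, camera adjusted p = 0.399). Of 14 stable RNA genes 0 were called by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median -0.10, camera adjusted p = 0.531). This was the ribosomal RNA gene MSMEG_4931 (-0.34, SE 0.15), with -0.19 without WT replicate 3 and -0.51 without KOmsoA replicate 1. The libraries were depleted of ribosomal RNA, so its counts are what depletion left and do not give the ribosomal RNA level. rplL lost its call without KOmsoA replicate 3 (edgeR adjusted p = 0.0645), and rpsP and argS without KOmsoA replicate 2 or 3 (up to 0.137). rpsF lost it without WT replicate 2 or any 1 KOmsoA library (up to 0.151), and aspS without any library but WT replicate 3 (up to 0.14). WT replicate 3 held 355 CPM of argS, against 277 and 261 CPM in the other WT libraries, and the log2 fold change of argS was -0.26 without it.

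Among stress responses, 5 of 22 oxidative stress and mycothiol genes fell, and 1 rose and 5 fell adjusted over the list alone (median -0.05, camera adjusted p = 0.426). They included mca, a mycothiol conjugate amidase gene (-0.24, SE 0.06), and the methionine sulfoxide reductase gene msrA (-0.21, SE 0.05). Of 14 heat-shock chaperone and protease genes 1 fell, the groL copy MSMEG_1583 (-0.17, SE 0.04), and 2 fell adjusted over the list alone. The median of that list was -0.03 and the camera direction lower (adjusted p = 0.765), while its mean was slightly above 0 (0.00). Of 14 SOS and DNA repair genes ruvB (0.30, SE 0.07) and recA (0.21, SE 0.05) rose, and 4 rose adjusted over the list alone (median 0.12, camera adjusted p = 0.146). Of 6 sigma and anti-sigma factor genes sigH fell (-0.18, SE 0.05), and 1 rose and 2 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.426). Of 6 osmoprotection and trehalose genes 0 were called by edgeR, 0 by DESeq2 and 1 by limma-voom, with 3 at an unadjusted p under 0.05. Adjusted over the list alone 1 rose and 2 fell (median 0.10, camera adjusted p = 0.765), and treZ had a log2 fold change of 0.16 (SE 0.05). msrA and recA lost their call without KOmsoA replicate 2 or 3, mca without these or WT replicate 2, and MSMEG_1583 without WT replicate 2, KOmsoA replicate 1 or KOmsoA replicate 3 (edgeR adjusted p up to 0.136). ruvB and sigH lost it without any library but WT replicate 3 and KOmsoA replicate 1 (up to 0.178).

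Among nutrient uptake genes, 4 of 14 nitrogen assimilation genes fell, and 1 rose and 5 fell adjusted over the list alone (median -0.13, camera adjusted p = 0.322). The ammonium transporter genes MSMEG_6259 (-0.60, SE 0.12, edgeR adjusted p = 0.0051) and MSMEG_2425 (-0.39, SE 0.05, edgeR adjusted p = 0.000471) fell most among the called members. Of 6 phosphate uptake genes pstS fell (-0.28, SE 0.07), also 1 adjusted over the list alone (median -0.01, camera adjusted p = 0.73). Of 15 siderophore and iron uptake genes the mycobactin gene MSMEG_4510 rose (0.62, SE 0.15), also 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.757). Of 6 genes listed by symbol under sulfur assimilation cysW rose (0.27, SE 0.08) and cysD fell (-0.23, SE 0.05), as they did adjusted over the list alone (median -0.04, camera adjusted p = 0.757). One of the 6 is cysS, the cysteinyl-tRNA synthetase gene. Without it 1 of 5 members rose and 1 fell, also adjusted over the list alone (median -0.08, camera adjusted p = 0.754). pstS, MSMEG_4510, cysW and cysD each lost their call without KOmsoA replicate 2. It was also lost for pstS without WT replicate 1 or KOmsoA replicate 1, and for MSMEG_4510 without WT replicate 1, WT replicate 2 or KOmsoA replicate 1. For cysW it was lost without WT replicate 2, KOmsoA replicate 1 or KOmsoA replicate 3, and for cysD without KOmsoA replicate 3 (edgeR adjusted p up to 0.144 among these genes), and for cysW with the replicate number as a block.

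Among envelope genes, 3 of 25 genes listed by symbol under peptidoglycan and cell division rose, and 4 rose and 1 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.186). They included ripD (0.47, SE 0.09) and ftsW (0.30, SE 0.07). This list holds ftsH, a membrane protease gene, and ftsY, a signal recognition particle receptor gene. Without these 3 of 23 members rose, and 4 rose and 1 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.22). Of 28 genes of the glycopeptidolipid locus 1 fell, MSMEG_0406 (-0.18, SE 0.03), also 1 adjusted over the list alone (median -0.05, camera adjusted p = 0.638). Of 17 genes listed under Mce transport MSMEG_0137 rose (0.27, SE 0.08) and MSMEG_0132 fell (-0.38, SE 0.08), as they did adjusted over the list alone. The median of that list was 0.02, its mean -0.02 and the camera direction lower (adjusted p = 0.76). One member, MSMEG_4921, entered by the symbol mce, which also names methylmalonyl-CoA epimerase. Without it 1 of 16 members rose and 1 fell, also adjusted over the list alone (median 0.02, mean -0.01, camera direction lower, adjusted p = 0.805). Of 5 drug efflux genes MSMEG_2619 fell (-0.34, SE 0.06), and 1 rose and 1 fell adjusted over the list alone. The median of 0.05 and mean of 0.03 were positive where the camera direction was lower (adjusted p = 0.805). Of the 11 ESX-3 secretion genes (median 0.11, camera adjusted p = 0.423) and the 10 ESX-1 genes (-0.03, 0.73) 0 were called by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, with 5 and 1 at an unadjusted p under 0.05. Their members with the smallest p were eccE (MSMEG_0626; 0.41, SE 0.15) and eccA1 (-0.17, SE 0.07). ftsW lost its call without WT replicate 2 or KOmsoA replicate 2, and MSMEG_0137 without any library but KOmsoA replicate 1 (edgeR adjusted p up to 0.175) and with the replicate number as a block.

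Called genes lay together on the chromosome. In locus order, 34 runs of at least 3 consecutive tested genes were all called in one direction, 22 higher and 12 lower, covering 120 genes. Permuted calls gave a mean of 1.98 and at most 10 runs (permutation test, p = 1e-04, the smallest that 10000 permutations can give). The longest run rose, 6 genes from MSMEG_3266 (0.32, SE 0.08) to derK (MSMEG_3271; 0.41, SE 0.11), with the largest change in MSMEG_3269 (0.52, SE 0.09). The 5 genes from MSMEG_2476 (0.43, SE 0.13) to MSMEG_2481 (0.76, SE 0.09) rose, MSMEG_2478 most (0.92, SE 0.13), as did the 5 from MSMEG_6765 (0.32, SE 0.09) to MSMEG_6769 (0.43, SE 0.09). The longest runs that fell included the 5 genes from MSMEG_4325 to MSMEG_4329 described above. The 5 genes from MSMEG_3939 (-0.49, SE 0.13) to MSMEG_3943 (-0.45, SE 0.11) hold the DosR list members MSMEG_3940 and MSMEG_3941, and MSMEG_3942 fell most (-0.66, SE 0.06). The 4 genes from MSMEG_6758 (-0.25, SE 0.06) to MSMEG_6760 (-0.38, SE 0.11) hold a glycerol kinase gene, the glpK copy MSMEG_6759 (-0.35, SE 0.06).

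The number of runs was 18 without WT replicate 1, 13 without WT replicate 2 and 46 without WT replicate 3. It was 17 without KOmsoA replicate 1, 13 without KOmsoA replicate 2 and 15 without KOmsoA replicate 3. Of the genes at the ends of the runs just named, MSMEG_2481 and MSMEG_4329 held their call with any 1 library left out. The others lost it without KOmsoA replicate 2 (edgeR adjusted p up to 0.211), MSMEG_3266 and MSMEG_6769 in that fit alone. derK and MSMEG_6765 lost it also without WT replicate 1, WT replicate 2 or KOmsoA replicate 3, and MSMEG_6758 without WT replicate 2 or KOmsoA replicate 3. MSMEG_2476 lost it without any 1 library, MSMEG_3939 and MSMEG_3943 without any but WT replicate 3, and MSMEG_6760 without any but WT replicate 1. DESeq2 did not call MSMEG_2476, MSMEG_3939 or MSMEG_6760. The calls of MSMEG_2476, MSMEG_6765 and MSMEG_3939 were lost with the replicate number as a block, that of MSMEG_2476 with upper-quartile factors and that of MSMEG_6760 with the gene span trend removed.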

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

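The gene span correction, the lists without symbol matches of another function, and the runs under RLE, upper-quartile, filter, stable RNA, DESeq2, limma-voom, glmTreat and strict-threshold settings, were chosen after seeing the data. The 663 gene calls became 572 to 699 under the other scalings, filters, tools, stable RNA and span settings, 2 with glmTreat against a log2 fold change of 1 and 293 at an adjusted p under 0.01, both by construction stricter tests. With 1 library left out they ranged from 327 to 797. They were highest without WT replicate 3 (797) and lowest without WT replicate 2 (407), KOmsoA replicate 2 (327) or KOmsoA replicate 3 (339). Among the called genes that a setting also tested, none changed sign; the 10 CPM filter tested 4463 genes and DESeq2 4422, against 5836. The 5 lists became 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 10 with fry, which adds hydrogenases, SOS and DNA repair, ESX-3, nitrogen assimilation and the glycopeptidolipid locus but does not compare a list with other genes; they were 4 to 5 with 1 library left out and 5 without symbol matches of another function. For the cholesterol and cytochrome bd lists the estimated correlation was 0.0067 and -0.39, below the preset 0.01. Their unadjusted camera p in that fit still rose from 0.00171 to 0.0338 and from 0.00512 to 0.0474. A higher correlation is thus argued against as the cause of these lost calls. The estimates for the DosR, mycolic acid and cycle lists lay above the preset value (0.165, 0.0544 and 0.232). Otherwise the cause of the differences between list tests was not tested. At a mean of at least 10 CPM the hydrogenases passed in place of cytochrome bd. The 34 runs became 0 with glmTreat, 11 at an adjusted p under 0.01, 12 at 4 or more genes and 13 to 46 with 1 library left out; the cause of the last range was not tested. The msoA alternatives were not run, since its locus is not named in the sources used here, and runs in locus order alone are the same as those reported because no strand was used. At these totals and with 3 libraries per strain, simulated changes of 0.5 on the log2 scale were recovered in 65% of cases. Whether depth or the number of libraries limits this was not tested.

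Replicate numbers did not pair the samples: same-numbered libraries had correlations of deviations of -0.0171, 0.0136 and -0.00416, and not every library correlated best with its own number. With the replicate number as a block, 598 genes, 5 lists and 29 runs were called.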

Other observations

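The fits with single libraries left out and with an estimated correlation were fixed before the data were examined. Their use to test explanations in this part, and all other tests of explanations here, were chosen after the results they bear on had been seen. The genes in the first 2 paragraphs were also chosen after their values were seen.

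Several shorter runs held genes of known pathways. The zinc transport genes aztD (0.67, SE 0.09), aztC (0.70, SE 0.10) and aztB (0.49, SE 0.08) rose together (edgeR adjusted p between 0.000433 and 0.00225), as did leuC (0.32, SE 0.05) and leuD (0.40, SE 0.06) of leucine synthesis, hutU (0.40, SE 0.05) of histidine breakdown and catA (0.45, SE 0.07) of catechol breakdown. The run MSMEG_0293 to MSMEG_0295 rose with a median log2 fold change of 0.99. On the other side of MSMEG_0296, which did not pass (0.23, SE 0.15), MSMEG_0299 (0.84, SE 0.11) and MSMEG_0300 (0.71, SE 0.07) rose. Their neighbours MSMEG_0297 (1.75, SE 0.25) and MSMEG_0298 (1.46, SE 0.38) also rose, from means of only 2.57 and 1.31 CPM in WT. Genes nrtR (-0.74, SE 0.10) and nadA (-0.49, SE 0.05), of NAD synthesis and its regulation, fell next to each other, as did araB (-0.39, SE 0.11) with MSMEG_1711 and MSMEG_1712.

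The most abundant genes after dnaK were the transfer-messenger RNA ssrA (2.55% ± 0.0506 of WT and 2.69% ± 0.0471 of KOmsoA counts, SD, n = 3), the disaggregase gene clpB (2.13% ± 0.0338 of KOmsoA counts) and groL MSMEG_0880 (1.23% ± 0.0392 and 1.17% ± 0.00704). None of these passed edgeR's test (adjusted p = 0.223, 0.143 and 0.052). Of 173 genes with an identical protein copy, 120 had a count of 0 in all 6 libraries, against 5 of the other genes, whose median total was 1029 counts. The 44 such genes at 1074818 to 1125650 and their 44 copies at 2368080 to 2418912 had 0 counts each, so expression of this duplicated segment was not measured in the count table.

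MSMEG_6731 was almost absent from KOmsoA and MSMEG_6732 far higher. A copy-number change of the whole region is argued against, since these genes changed in opposite directions and the 20 tested flanking genes had a median log2 fold change of 0.0127 (4 called). The flanking genes do not bear on a change confined to MSMEG_6731 or MSMEG_6732. Among 4905 genes with at least 100 WT counts, 1 gene, MSMEG_6731, lay under 5% of WT, the next lowest being MSMEG_1320 at 28.7%. Whether MSMEG_6731 is the gene disrupted in this mutant, or is silenced in it, was not tested. Whether the rise of MSMEG_6732 and MSMEG_6729 on either side could follow from loss of a regulator or from transcription out of a construct placed at the locus was not tested, since neither strand nor read positions were used here.

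The DosR list was lower in KOmsoA. The divergent WT replicate 3 is argued against as the cause, since without it the list median was -0.28 (camera adjusted p = 1.28e-06, range over leave-one-out fits 1.28e-06 to 0.000867). A trend with gene span is also argued against, since log2 fold changes hardly followed span over all tested genes (Spearman correlation 0.036). Little was thus there to remove, and with the trend removed the list median was -0.26 (camera adjusted p = 4.74e-05). An effect of the mutation and a difference between the cultures at harvest both stay open and were not tested. The list passed camera at the preset correlation of 0.01 but not with an estimated one (0.165, camera adjusted p = 0.427). Lists with an estimate below 0.01 lost their call in that fit too. How far correlation between the members accounts for the loss was not tested.

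Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 663 genes, 5 lists and 34 runs. The highest of the other splits gave 0 genes (edgeR, 91 to 253 at an unadjusted p under 0.05, against 1533), 3 lists and 0 runs. For each count 1 split, the real one, was thus as large. Some of the other splits, with 0 genes called, still gave 2, 2, 1 and 3 lists by camera. Each of the other splits mixes the strains and so puts the strain difference into the spread within its groups. The 0 genes there therefore do not measure what chance gives.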
